A study of Homo sapiens with 18 samples.

How the data were processed

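In-cell SHAPE probing with 2A3, an acylating reagent that reacts with the 2′-hydroxyl of flexible nucleotides, was read out on human 18S rRNA in MDA-MB-231 cells, an established breast cancer line. Cells carried a scrambled control (SCR) or 1 of 2 knockdowns, called FBL1 and FBL2 after the labels. They are read here as 2 knockdown lines of fibrillarin, which the labels do not spell out. The series title concerns fibrillarin, the methyltransferase that places 2′-O-methyl groups on rRNA. Each line was treated with 2A3 or with DMSO as background for 15 min at 37 °C, and each RNA was amplified with 3 primer sets and sequenced on a nanopore instrument, per the labels' protocols and the series' design text. This gives 18 libraries, with 1 library per line, reagent and primer set. Duplicate wells are mentioned in the design text, and whether a library pools them is not given in the sources used here. Primer sets cover different stretches of the rRNA and were not treated as replicates. The amount of fibrillarin is not measured by these libraries.

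Bowtie2 and SAMtools are named in the submitters' processing notes, without versions. The reference build and the kind of sequence event that was counted are not given in the sources used here. The deposited reactivity is a fraction of reads with an event at each position, rounded by the authors to steps of 0.1% when written as a percent. The deposited coverage is the read depth per position, a signal that is never negative. The deposited error equals the square root of reactivity over depth and is 0 where reactivity rounds to 0. The authors' deposited difference of 2A3 and DMSO, in percent, and its error in percent, are given in most 2A3 files and were recomputed here from the deposited fractions for every library. Positions are those of the files, from 1 to 1869 of 18S rRNA.

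Primer set 1 covered positions 1155 to 1840, primer set 2 positions 614 to 1273 and primer set 3 positions 25 to 815. Depth per position ran from 98418 to 280361 reads in primer set 1, from 356621 to 644764 in primer set 2 and from 165795 to 459123 in primer set 3. At a reactivity of 1% and the median depth of a library the counting error lay between 0.0125% and 0.0310%, below the largest rounding error of 0.05%. PCR reads without molecular identifiers are not independent molecules, so the errors cover counting only. A reactivity listed at 0 means under 0.05%.

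The DMSO value was subtracted from the 2A3 value at each position with a depth of at least 100 reads. Each library pair was then scaled so that the mean of its values between the 90th and 98th percentiles equals 1, which defines the normalized unit. A position was called risen or fallen when the knockdown minus SCR difference was at least 0.3 normalized units in the same direction in both knockdowns and exceeded 1.96 times the summed errors in both. This is a rule of size. With 1 library per group no test across libraries is possible and no p-value is given. On simulated data with counting noise at the real depths, the rule called 31 of 33 simulated changes of 0.4 units in primer set 1 and 33 of 33 in each of the other sets. It called 0 of 619, 0 of 593 and 0 of 724 unchanged positions in primer sets 1, 2 and 3. Apart from the simulated changes, lines differed there only by depth, counting noise and 1 gain factor for all positions. Gains that differ between bases and other variation between libraries were not simulated, so the rate of false calls in the real libraries is not known.

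A list of 41 known 2′-O-methylation sites of 18S rRNA was fixed before the data were examined. All 41 lay in the measured stretches and had the listed base. The median change over the list was set against 10000 random lists matched on base and primer set. The correlation of the FBL1 and FBL2 differences was set against 200 simulations in which all lines had the SCR reactivities, because both differences use the same SCR library. Positions named in the text were chosen by a rule fixed before the data were examined: per primer set the 4 largest rises and 4 largest falls that passed the size rule, listed 2′-O-methylation sites that passed it, the 2 listed sites with the largest mean rise and the 2 with the largest mean fall, the listed base-modified positions, and the position with the highest DMSO value in SCR. Other positions are named as chosen after their values were seen.

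Alternatives covered the DMSO subtraction, 3 other scalings, stretch ends, positions of high DMSO signal, a depth minimum of 1000 reads, a sliding mean of 3 positions, either knockdown or any primer set left out, thresholds of 0.2 and 0.5, and each knockdown in the place of SCR. A median-ratio scaling, 1 factor per base and a criterion with rounding error were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.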

Results

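Reactivity to 2A3 was measured along 18S rRNA in SCR, FBL1 and FBL2 cells, each beside its DMSO background. The 3 primer sets gave 2137 measurements per line at 1816 distinct positions, since 202 positions lie in both primer sets 2 and 3 and 119 in both primer sets 1 and 2. Each value comes from 1 library and has no replicate, and errors after ± are the deposited counting errors.

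The first comparison asked how far 2A3 raised the signal above DMSO in each line. Mean signal above background was higher in both knockdowns than in SCR in every primer set. In primer set 3 the mean 2A3 minus DMSO reactivity was 0.561% in SCR, 0.740% in FBL1 and 0.622% in FBL2. In primer set 2 it was 0.358%, 0.512% and 0.441%, and in primer set 1 it was 0.207%, 0.331% and 0.268%, in the same order. Relative to SCR, FBL1 was 1.32-fold to 1.60-fold higher and FBL2 1.11-fold to 1.29-fold higher. At positions with at least 1% signal in SCR the median ratio was smaller, at 1.17 to 1.26 in FBL1 and 1.05 to 1.10 in FBL2. Uridines carried the highest mean signal of the 4 bases in primer set 3, at 0.935% in SCR, 1.28% in FBL1 and 1.10% in FBL2. In primer set 1 cytidines carried the highest, at 0.303%, 0.396% and 0.338%. Mean DMSO reactivity stayed between 0.202% and 0.271% in all 9 DMSO libraries. These means include G60 and U1248, which have very high DMSO values. Without them the means in SCR, FBL1 and FBL2 were 0.136%, 0.149% and 0.150% in primer set 3. They were 0.125%, 0.137% and 0.136% in primer set 2, and 0.137%, 0.137% and 0.138% in primer set 1. The share of positions higher in 2A3 than in DMSO was lowest in SCR primer set 1, at 47.4%, where 345 of 686 positions had equal rounded values. In primer set 3 this share was 70.9% in SCR, 77.0% in FBL1 and 70.7% in FBL2. The mean cytidine signal there was 0.511%, 0.577% and 0.508%, so FBL2 was not above SCR by either measure.

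**Figure D1:**
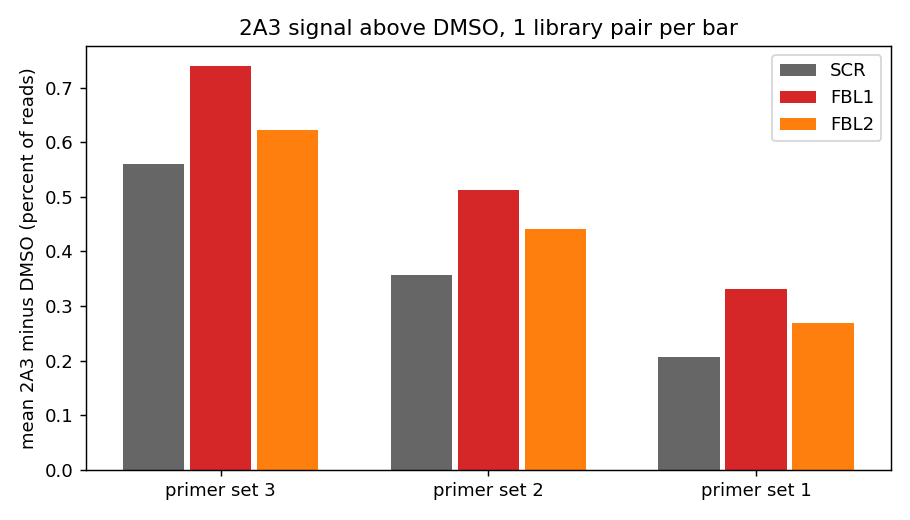
Mean 2A3 minus DMSO reactivity, in percent of reads, for SCR, FBL1 and FBL2 in each primer set, with 1 library pair per bar and no error bar because there are no replicates. Both knockdowns lie above SCR in each primer set, with FBL1 highest.

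The next comparison asked which nucleotides became more or less reactive in both knockdowns after libraries were scaled to a common range. The rule called 41 rises and 27 falls, at 38 and 26 distinct positions. Primer set 1 had 18 rises and 7 falls, primer set 2 had 14 and 13, and primer set 3 had 9 and 7. The normalized unit in SCR equalled 0.970%, 1.68% and 3.02% of reads in primer sets 1, 2 and 3. In percent of reads the size threshold was thus lowest in primer set 1 and highest in primer set 3. Counts are therefore not comparable between primer sets. Adenosines made up 17 of the rises and uridines 14, while cytidines made up 15 of the 27 falls and 1 of the 41 rises, against 31.3% of the positions with at least 1% signal in SCR. With 1 scale factor per base, cytidines made up 7 of 36 falls and 4 of 28 rises. With FBL1 in the place of SCR, the same rule called 26 positions, and with FBL2 13, against 68 with SCR as the line set apart. The split depended on scaling. Without scaling between libraries there were 67 rises and 7 falls, with the 90th percentile 30 and 32, and with box-plot scaling 9 and 72. Scale factors were higher in both knockdowns than in SCR in every primer set. Leaving out the scaling thus raises knockdown values that are above 0 and lowers those below 0. All 41 rises and 6 of the 27 falls then passed, and 20 of the 27 falls still lay below SCR in both knockdowns. Under all 5 scalings compared, 9 rises and 6 falls passed. Those 9 rises were 0 of 18 in primer set 1, 3 of 14 in primer set 2 and 6 of 9 in primer set 3, since box-plot scaling ended most calls.

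**Figure D2:**
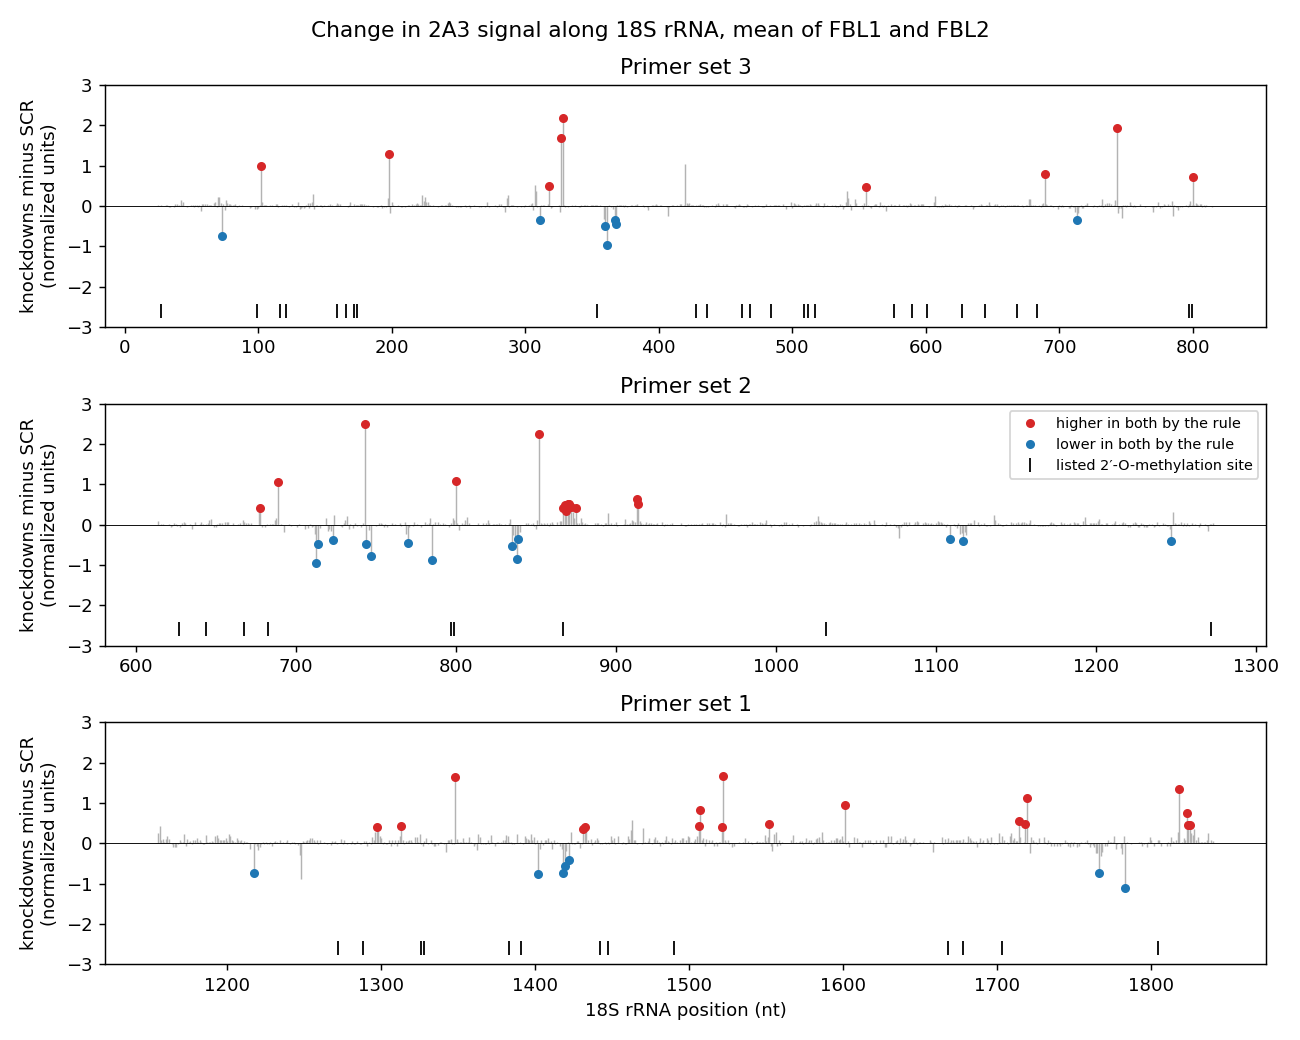
Mean of the FBL1 and FBL2 differences from SCR, in normalized units, against 18S rRNA position, with 1 panel per primer set. Red and blue points mark the 41 rises and 27 falls, and ticks mark the listed 2′-O-methylation sites.

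In the 5′ part of the rRNA, covered by primer set 3, the largest rise was at U328. Its 2A3 reactivity was 13.6% ± 0.080 in SCR, 23.6% ± 0.11 in FBL1 and 20.6% ± 0.099 in FBL2. The neighbouring G327 rose from 9.0% ± 0.065 to 16.9% ± 0.092 and 13.9% ± 0.081, and U198 from 6.3% ± 0.055 to 12.5% ± 0.080 and 9.9% ± 0.070. The largest fall was at U361, from 8.0% ± 0.061 to 4.9% ± 0.049 in FBL1 and 6.2% ± 0.054 in FBL2. A360 and U368 were also among the falls, in a group of 4 between positions 360 and 368, and C73 fell from 12.1% ± 0.080 to 10.7% ± 0.077 and 10.9% ± 0.076. Unscaled, A360 and U368 missed the size threshold but stayed below SCR, at 0.824-fold and 0.868-fold in FBL1 and FBL2 for A360 and at 0.918-fold and 0.787-fold for U368. With the sliding mean U198, C73 and U368 no longer passed, at 0.359, -0.285 and -0.303 units.

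In the middle stretch, covered by primer set 2, U743 had the largest rise, from 14.7% ± 0.054 in SCR to 24.0% ± 0.071 in FBL1 and 21.9% ± 0.076 in FBL2. Primer set 3 also covers U743 and gave 13.3% ± 0.083, 21.4% ± 0.11 and 20.3% ± 0.10. G852 rose from 7.2% ± 0.038 to 13.5% ± 0.053 and 13.1% ± 0.059, U800 from 3.4% ± 0.026 to 6.9% ± 0.038 and 5.8% ± 0.039, and U689 from 5.8% ± 0.034 to 10.6% ± 0.047 and 7.8% ± 0.046. Between positions 867 and 875 there were 7 rises, none of which passed with box-plot scaling. Nor did U743 and U689 in this primer set, at 0.456 and 0.215 units, whereas U743 passed in primer set 3. With the sliding mean U689, U747 and C785 no longer passed, at 0.333, -0.331 and -0.320 units. C713 fell from 5.1% ± 0.032 to 4.3% ± 0.030 and 4.2% ± 0.034, and U747 from 3.7% ± 0.027 to 2.8% ± 0.024 and 3.0% ± 0.028. C785 and G838 were the other large falls of this stretch. The fall at C785 is relative, since its unscaled signal was 1.10-fold and 0.990-fold that of SCR in FBL1 and FBL2. The ratios for G838 were 0.869 and 0.984. Neither C785 nor G838 passed unscaled or with the 90th percentile.

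In the 3′ part, covered by primer set 1, A1522 rose from 3.1% ± 0.038 in SCR to 5.6% ± 0.073 in FBL1 and 5.3% ± 0.053 in FBL2. A1818 rose from 0.8% ± 0.019 to 2.7% ± 0.051 and 2.2% ± 0.034, and A1719 from 0.6% ± 0.017 to 2.1% ± 0.045 and 1.8% ± 0.031. G1348 rose from 9.3% ± 0.069 to 13.1% ± 0.11 and 12.2% ± 0.081, but its direction turned with the 90th percentile and with box-plot scaling, as did that of A1522 with box-plot scaling. G1348 also no longer passed without DMSO subtraction, at 0.646 units, or with the sliding mean, at 0.145 against 1.64. A1217 fell from 0.9% ± 0.022 to 0.3% ± 0.017 and 0.2% ± 0.011, while primer set 2 gave no fall there. With the sliding mean A1217 no longer passed, at -0.257 units. C1783, C1418 and A1402 were the other large falls. The unscaled signal of C1783 was 1.06-fold that of SCR in FBL1 and 0.977-fold in FBL2, and that of C1418 was 1.02-fold in FBL1 and equal in FBL2. Unscaled, the mean change of both was above 0. A1402 stayed below SCR unscaled, at 0.571-fold and 0.905-fold, with a mean change of -0.567 against -0.759 units when scaled, and no longer passed in both lines. Chosen after their values were seen, A1824 and A1825, adenosines of the decoding centre, also rose, within a group of 4 rises between positions 1818 and 1825. Signal at A1824 and A1825 rose by 0.6% of reads in FBL1 and 0.5% in FBL2, from values near the rounding step of 0.1%. Ratios to SCR were 4 and 3 in FBL1 and 3.5 and 2.67 in FBL2. Rounding could lower them to 2.33 and 2 in FBL1 and to 2 and 1.75 in FBL2. A1824 and A1825 did not pass with the 90th percentile, and none of the 4 passed with box-plot scaling.

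The 202 positions shared by primer sets 2 and 3 allowed the same RNA to be read from separate amplicons. Signals correlated across positions with r between 0.996 and 0.997 in each line, and the changes from SCR with r = 0.930 in FBL1 and 0.914 in FBL2. Primer set 2 called 11 of these positions and primer set 3 called 4, where the size threshold is higher in percent of reads. The 4 shared calls, U689, C713, U743 and U800, had the same direction in both. The overlap of primer sets 1 and 2, where mean signal was under 0.14% in each line without U1248, gave r = 0.545 and 0.116 for the changes, and no shared call. Positions are not independent replicates.

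The comparison at the listed 2′-O-methylation sites addressed whether nucleotides that fibrillarin methylates became more reactive in FBL1 and FBL2, read here as fibrillarin knockdowns. Over the 41 sites, measured 48 times, the median change was 0.0156 normalized units, at percentile 77.2 of the random lists. It was 0.0266 in FBL1 and 0 in FBL2. Without DMSO subtraction the median turned to -0.00254, at percentile 13.8. A log2 ratio of 2A3 values, which also leaves out the DMSO subtraction and the scaling, had a median of 0.0902, at percentile 14.3. Alternatives that kept the subtraction lay between percentiles 54.4 and 89.5. The percentile thus depended on the subtraction, and no direction of the list was settled. The negative median appeared only where unsubtracted values were scaled. Um1326 had a 2A3 value of 0.2% in SCR, FBL1 and FBL2, yet was at -0.0439 units there, through the scaling alone. Only Gm867 passed the size rule, from 0.7% ± 0.012 in SCR to 1.7% ± 0.019 in FBL1 and 1.6% ± 0.021 in FBL2, and the other 47 measurements did not. Over all measurements the rule called 41 rises among 2137. Gm867 belongs to the group of 7 rises between positions 867 and 875, whose other members are not listed sites. Its rise is thus not particular to the listed nucleotide. The call at Gm867 was lost with box-plot scaling, at 0.284 units, and with the sliding mean, at 0.294. The sliding mean newly called Um799 as a rise, at 0.406 units. Its window holds U800, which changed by 1.08 units, against 0.124 at Um799 itself. Both knockdowns lay above SCR in 13 measurements, both below in 9 and neither in 26. Of the measurements below, only Am99 was lower before scaling. The others had equal 2A3 minus DMSO values in SCR, FBL1 and FBL2, so they were lower through the scaling alone. Gm683 in primer set 3, counted above, also had equal unscaled values. Median 2A3 reactivity at the listed sites in SCR was 0.25%, close to the rounding step of 0.1%. Small changes were thus not detectable at this rounding. The SCR level of the list lay at percentile 5.47 of the random lists. By primer set it lay at percentile 28.8 in primer set 1, 62.3 in primer set 2 and 0.49 in primer set 3.

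Among the other listed sites, Cm1703 had 0.4% in SCR, 1.1% in FBL1 and 0.7% in FBL2, and its DMSO reactivity was 0.2%, 0.5% and 0.4%. Um1668 had 0.1%, 0.3% and 0.2%, and Um799 had 0.3%, 0.5% and 0.5%. Am159 had 1.5%, 1.6% and 1.6% over DMSO values of 1.4%, 1.3% and 1.2%, and Um172 had 0.3%, 0.4% and 0.3%. The sites with the largest negative means were Am99 and Am166 in primer set 3, Um627 and Gm683 in primer set 2, and Um1326 and Um1442 in primer set 1, none beyond 0.1 units in size. Unscaled, the mean change at Um627, Gm683, Um1326 and Um1442 was 0, so their negative means came from the scaling.

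Of 7 listed base-modified nucleotides, 4 were measured and 3 lay outside the stretches. None of the 4 showed a change that passed the rule in the main setting. U1248 passed as a fall without DMSO subtraction, at -13.8 units with primer set 1 and -5.44 with primer set 2, and without scaling at -1.39 with primer set 1. Its 2A3 values in SCR, FBL1 and FBL2 were 52.0%, 49.2% and 48.9% with primer set 1. With primer set 2 they were 50.8%, 50.8% and 51.2%, so that fall came from the scaling. With FBL2 alone U1248 passed as a fall of -1.09 with primer set 1 and as a rise of 0.470 with primer set 2. U1248, which carries a hypermodified pseudouridine, had events in 54.2% of DMSO reads in SCR, 52.8% in FBL1 and 52.4% in FBL2 with primer set 1, and in 50.9%, 50.6% and 50.4% with primer set 2. It had the highest DMSO value of both stretches. C1337, an acetylated cytidine, had 2A3 values of 0.4%, 0.5% and 0.3%. G1639, a 7-methylguanosine, had 0.3%, 0.5% and 0.4%, and A1832, an N6-methyladenosine, had 0.2%, 0.4% and 0.1%. The highest DMSO value of primer set 3 was at G60, with 95.4% in SCR, 95.5% in FBL1 and 95.4% in FBL2. G60 passed as a fall without DMSO subtraction, at -2.37 units. Its 2A3 values were 94.5% in SCR, 94.8% in FBL1 and 94.4% in FBL2, so that call also came from the scaling.

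The last comparison asked whether the FBL1 and FBL2 lines changed alike. Across all measurements the differences from SCR correlated with r = 0.852 and rho = 0.672, against a mean r of 0.389 in simulations with no change, which hold counting noise only. The covariance was 0.0288, against 0.000131 in the simulations, a difference of 0.0287. Rises numbered 70 in FBL1 alone and 52 in FBL2 alone with 41 shared, where independent lists would share 1.70, a value that leaves out the shared SCR library. Falls numbered 39 and 29 with 27 shared, where independent lists would share 0.529. Both values for independent lists treat every measurement as equally able to pass. Only 179 of 2137 measurements had at least 1% signal in SCR, and positions near background can hardly reach the size threshold. More overlap than 1.70 and 0.529 is thus given by the rule itself, and these contrasts do not measure agreement. No position passed in opposite directions. The single SCR library could not be split. A deviation of that library from other SCR cultures would enter both differences, so part or all of the excess may come from the shared control.

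**Figure D3:**
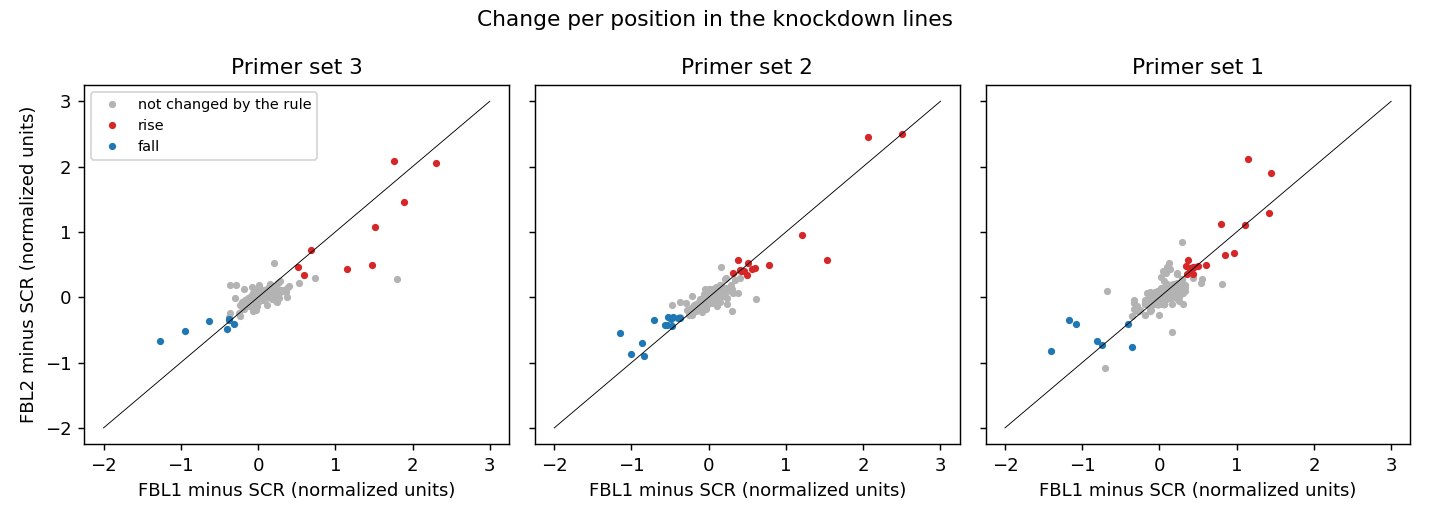
Difference from SCR in FBL2 against that in FBL1, in normalized units, with 1 point per position and 1 panel per primer set. Called positions lie in the same direction in both lines, and the diagonal marks equal change.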

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

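At 2 positions in the overlap of primer sets 1 and 2, the sign of the change differed between the amplicons, with both knockdowns on the same side each time. The difference was not tested. At A1217 the mean change was -0.736 normalized units with primer set 1 and 0.0642 with primer set 2, where 2A3 values of 0.3%, 0.6% and 0.5% in SCR, FBL1 and FBL2 stood over DMSO values of 0.2%, 0.4% and 0.2%. The change with primer set 2 is about the size of the rounding step of 0.1%, so a move in the other direction is not shown there. At U1248 it was -0.895 with primer set 1 and 0.311 with primer set 2, over a DMSO background near 50% of reads, and neither value passed the size rule. Without DMSO subtraction U1248 passed as a fall with both primer sets, at -13.8 and -5.44. The fall with primer set 2 came from the scaling, since 2A3 values were 50.8%, 50.8% and 51.2% in SCR, FBL1 and FBL2. The sign at U1248 depended on the processing, since box-plot scaling gave 0.836 with primer set 1 and the sliding window gave -0.0251 with primer set 2.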

How the results depend on the processing

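No paired analysis was possible because each group has 1 library and no test was run. Against 41 rises and 27 falls, box-plot scaling gave 9 and 72, no scaling 67 and 7, a threshold of 0.5 gave 17 and 9, FBL1 in the place of SCR 11 and 15, and FBL2 in its place 2 and 11. Rises numbered 62 at a threshold of 0.2 and 70 without the FBL2 knockdown. Fewer positions remained without primer set 1, with 23 rises, and without primer set 2, with 27 rises and 14 falls. Both counts stayed within 1.5 times under the other alternatives, including those added after seeing the data: 43 and 22 with median-ratio scaling, 28 and 36 with 1 factor per base, and 39 and 26 with rounding error added. The median 2A3 over DMSO ratio was 1.5 in SCR and 2 in FBL1 and FBL2. As a ratio of means, which includes G60 and U1248, it was 2.70, 3.30 and 2.93. A sliding window gave 2.33 in FBL1, and FBL2 without primer set 3 gave 1.67. SCR had 1 without primer set 3 and 2 without primer set 1, where it equalled both knockdowns. Without DMSO subtraction the 2′-O-methylation site shift turned to -0.00254, at percentile 13.8. As a log2 ratio of 2A3 values, also without DMSO subtraction and unscaled, it stayed above 0, at percentile 14.3. Under the other alternatives, which kept the subtraction, its percentile lay between 54.4 and 89.5. Agreement of the knockdowns, 0.852, was 0.950 without DMSO subtraction, 0.945 with box-plot scaling and 0.672 as Spearman's rho. The value of 0.950 includes U1248 at -13.8 and -5.44 units and G60 at -2.37. The value of 0.945 comes with 72 falls against 9 rises, a shift of both lines together. Neither was read as closer agreement of the lines. At single named positions, box-plot scaling turned A1522 to -0.940 and G1348 to -4.46, and the 90th percentile turned G1348 to -0.817. No scaling turned C1783 to 0.155, C1418 to 0.0516 and C785 to 0.268. Of 410 values at named positions, 376 stayed on the same side of the size rule, 21 no longer passed, 7 passed newly and 6 reversed. Part of the 376 belong to named positions that were not called. Some of those lay far below the threshold, such as Um1326 at -0.0139 units, and could hardly cross it. The share that stayed is thus not a measure of how stable the calls are. Leaving out a knockdown relaxes a rule that asks for both lines, so it cannot end a call. Values on the same side numbered 40 of 42 without FBL1, 42 of 42 without FBL2 and 42 of 42 with the depth minimum. These say nothing on how stable the calls are. Without DMSO subtraction, the newly passed falls at U1248 with primer set 2 and at G60 came from the scaling. The cause of the other shifts was not tested. A depth minimum of 1000 reads removed no position. Scaling has no bearing on the raw 2A3 over DMSO ratio, and leaving out a primer set or a knockdown gives no value for a single position or for the agreement of both lines, respectively. Rounding to 0.1% limits values near background more than depth does.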

Other observations

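All tests of explanations in this part were chosen after the results had been seen.

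DMSO reactivity itself differed between SCR and both knockdowns by at least 0.2% at 14 measurements, 6 up and 8 down, a selection made after seeing the data. C570 had 0.3% in SCR, 0.9% in FBL1 and 0.6% in FBL2. G789 had 0.4%, 1.2% and 0.8% with primer set 3 and 0.6%, 0.9% and 0.9% with primer set 2. A724 had 1.1%, 0.6% and 0.5% with primer set 2 but 0.6%, 0.6% and 0.7% with primer set 3. At the listed site Cm1703 the values were 0.2%, 0.5% and 0.4%. U1714 and G1718 were called risen partly over a lower DMSO value, which was 0.5%, 0.3% and 0.3% at U1714 and 0.6%, 0.4% and 0.4% at G1718.

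Mean signal above DMSO was higher in both knockdowns in every primer set. A single gain factor per library is argued against as the whole explanation. The median log2 ratio to SCR was higher for uridines than for cytidines, with a lower 95% bootstrap bound of 0.17. A common gain as part of the rise stays open, since this difference cannot exclude it. Median ratios to SCR for U, G, A and C were 1.33, 1.25, 1.15 and 1.09 in FBL1. In FBL2 they were 1.21, 1.11, 1.10 and 1. PCR and sequencing of single amplicons were tested over the positions shared by primer sets 2 and 3. For FBL1 the log2 ratios differed by 4.27% of the smaller one, with a 95% bootstrap interval of 0.239% to 22.9%. This argues against that explanation for FBL1 in primer sets 2 and 3. For FBL2 they differed by 44.7% with no upper bound, which leaves it open. Primer set 1 was not tested. Where it overlaps primer set 2, without U1248, primer sets 1 and 2 gave 2-fold and 1.71-fold in FBL1 and 1.525-fold and 1.38-fold in FBL2. With 1 library per line, reagent and primer set, a difference in probing between lines and an effect of the knockdown cannot be separated.

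Cytidines were frequent among the falls and rare among the rises. A gain that differs between bases is a candidate explanation: with 1 factor per base, 7 of 36 falls were cytidines, or 19.4%, below their share of 31.3% among positions of at least 1% in SCR. Scaling by base also removes a change common to all cytidines, so an effect of the knockdown on cytidines stays open.

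The 4 rises between positions 1818 and 1825 include the decoding centre adenosines A1824 and A1825. A change of the DMSO background is argued against, because the largest DMSO change at the 4 positions was 0% of the signal change. An artefact of stretch ends cannot be told apart from a change in the rRNA: the other 5 stretch ends held 1 changed position together. That position, U800 in primer set 3, was called in the same direction inside the stretch of primer set 2, so it gives no example of such an artefact. No other primer set reads the end near 1825.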
